A study of Mus musculus with 8 samples.

How the data were processed

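Hearts of 129/Sv mice on the control diet (4 libraries) and on the adenine diet (4 libraries) were compared at the level of mRNA. Per the labels' protocols, RNA was isolated with a phenol-based reagent and libraries were made with a NEBNext Ultra kit. The submitters' processing notes name FastQC 0.11.9, STAR 2.7.6a and the GRCm38.p6 genome. The counting program, the annotation, its strand setting and any filter before deposit are not given in the sources used here. The deposited table holds raw read counts per gene, whole numbers that the authors did not scale, with an Ensembl identifier and a symbol for each of 27304 genes, of which 991 had no read in any library. Groups and replicate numbers were taken from the sample titles. Identifiers were matched to a GENCODE annotation of GRCm38 for coordinates and overlaps, and 27225 of them matched. The mitochondrial genes were given their reference symbols by identifier.

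Counts were tested in R 4.3.3 with edgeR 4.0.16. Genes passed the default low-count filter by group, libraries were scaled by TMM factors, and a quasi-likelihood F-test of the diet gave log2 fold changes (adenine minus control), standard errors derived from the F statistic, and p-values adjusted by the Benjamini-Hochberg method over the 20093 genes tested. An adjusted p under 0.05 was called. CPM values are counts scaled to library size with the TMM factors, given as mean ± SD over libraries. The common biological coefficient of variation was 0.293. Total counts of 15626620 to 33886385 per library put a gene at 1 CPM on roughly 16 reads in the shallowest library, so values below that carry large counting error.

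46 gene lists on redox biology, hormone response, metabolism, cardiac function, inflammation and cell types were fixed before the data were examined. They were tested with camera at a preset inter-gene correlation of 0.01, with p-values adjusted over the lists, and again with an estimated correlation and with fry, whose p tests whether a list's genes move, on balance, one way. The median log2 fold change of each list was set against 10000 random lists whose members were drawn from windows of 200 genes of like abundance. In the lymphocyte list 4 of 18 symbols had no match. Principal components were computed from log2 CPM (prior count 2) of the 500 most variable genes, and group differences were tested by exact two-sided permutation over the 70 assignments. The rule for named genes was fixed before the data were examined: up to 10 genes per direction with the largest change and up to 5 with the lowest p among called genes with a mean of at least 1 CPM, no overlap between diets and a gene name, the 5 with the lowest p where none passed, and up to 4 called or otherwise up to 2 members with the lowest p per list. Fkbp5, Zbtb16, Ddit4, Map3k6, Sgk1, Gpnmb, Itgax, Atp6v0d2, Myh6, Arntl, Dbp, Myl4, Myl7, Hmox1, Nppa and Bpgm, and list members given without a standard error, were chosen after their values were seen. 1 gene that the rule names is not reported here.

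The fits were tested on simulated counts with the real means, library sizes and dispersions. For adenine against control, 200 of 19706 genes were changed, drawn from those with a mean of at least 1 CPM. Among changes whose direction it estimated rightly, edgeR recovered 57.6% of those of 1 log2 unit and 92% of those of 2 log2 units. It made 11 false calls among 160. DESeq2 recovered 64% and 96%, taken over all changes, with 25 false calls among 185. A list lowered by 0.5 log2 units in the simulation was called by camera and 0 of the other lists were. Genes were drawn independently there, and neither a library that stands apart nor a dependence of fold change on abundance was built in. The numbers of false calls hold only for such data. The simulation therefore cannot show how often camera calls lists whose genes move together, such as the erythroid list, with an estimated correlation of 0.673.

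Alternatives fixed before the data were examined were DESeq2 size factors, upper-quartile factors, removal of mitochondrial transcripts, the DESeq2 1.42.0 Wald test, limma-voom (limma 3.58.1), robust edgeR, no filter, a filter of 1 CPM in 4 libraries, each library left out, the replicate number as a block, 1 surrogate variable (sva 3.50.0), other thresholds, and other settings of the list tests and principal components. Added after seeing the data were the receptor background as a covariate, removal of both replicates numbered 2, removal of GC and length trends, and thinning to the smallest total. The surrogate variable ran from -0.092 to 0.55 in the controls and from -0.68 to 0.23 in the adenine libraries. Adjusting for it can therefore also remove part of a diet difference. Replicates of a group differed by far more than sampling noise, with a chi-square per gene of 20.4 to 98.4, so none was treated as a duplicate.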

Results

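Gene expression was measured by bulk RNA sequencing in hearts of male 129/Sv mice, an inbred strain, after 13 weeks on a control diet or on a diet with 0.15% adenine. Dietary adenine injures the kidney, because a poorly soluble product of it crystallises in the renal tubules, and is used to bring about chronic kidney disease. The series consists of 4 control libraries and 4 adenine libraries, and its title places it in the study of cardiac oxidative stress in kidney disease. Total counts were 31023879, 33886385, 27556228 and 24107554 in control 1 to control 4 and 27376156, 15626620, 29831706 and 25008698 in adenine 1 to adenine 4. Mitochondrially encoded transcripts took 34.2 ± 2.17% of counts in the controls and 38.0 ± 3.93% in the adenine libraries (SD, n = 4; exact two-sided permutation p = 0.286). The labels do not say that the libraries came from separate animals, so every p-value measures only the spread between these samples, which may be technical. Of 27304 genes in the table, 20093 passed the low-count filter and were tested.

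The comparison of the diets asked which cardiac transcripts differ in mice with adenine-fed kidney disease. 8 genes rose on the adenine diet at an adjusted p under 0.05 in edgeR and 0 fell. Passing over all genes refers to this edgeR test below, unless another tool is named. Resf1, a factor in retroelement silencing, rose from 23.4 ± 2.54 to 79.6 ± 6.62 CPM (SD, n = 4 per diet), with an adjusted p of 0.000231. Per1, a core repressor of the circadian clock and a glucocorticoid target, rose from 19.1 ± 2.10 to 73.0 ± 26.1 CPM, and Depp1, a target of FOXO transcription factors, from 23.8 ± 5.28 to 76.0 ± 18.3 CPM. Mmp12, the elastase of macrophages, rose from 1.91 ± 0.404 to 68.7 ± 64.5 CPM, with 7.70 CPM in the lowest and 160 CPM in the highest adenine library. In each of the 8 genes, all 4 adenine libraries lay above all 4 control libraries.

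The log2 fold changes, adenine minus control, were 1.77 (SE 0.14) for Resf1, 1.93 (SE 0.22) for Per1, 1.67 (SE 0.20) for Depp1 and 5.17 (SE 0.69) for Mmp12, which had 4.32 without adenine 3. The other 4 genes were Tent5b, a poly(A) polymerase, with 2.62 (SE 0.34), Myot, a protein of the sarcomeric Z-disc, with 1.22 (SE 0.16), Acer2, a ceramidase, with 1.17 (SE 0.17), and Cdkn1a, which encodes the cell cycle inhibitor p21, with 0.98 (SE 0.15). Adjusted p-values were 0.00963 for Per1 and Depp1, 0.0167 for Tent5b, 0.0182 for Mmp12 and Myot, 0.0257 for Acer2 and 0.0482 for Cdkn1a (edgeR quasi-likelihood test). On the GRCm38 assembly, Resf1 (ENSMUSG00000032712) spans 149309414 to 149335663 and Depp1 (ENSMUSG00000048489) 116650609 to 116652794, both on chromosome 6. Per1 (ENSMUSG00000020893) spans 69095217 to 69109960 on chromosome 11, Mmp12 (ENSMUSG00000049723) 7344381 to 7369499 on chromosome 9. Myot (ENSMUSG00000024471) spans 44334074 to 44355724 on chromosome 18 and Cdkn1a (ENSMUSG00000023067) 29090976 to 29100727 on chromosome 17. Tent5b (ENSMUSG00000046694), from 133480132 to 133487938, and Acer2 (ENSMUSG00000038007), from 86874396 to 86934822, lie on chromosome 4. Exons of Mmp12 overlap Mmp1b and exons of Cdkn1a overlap AC167363.2 on the opposite strand, and whether the counting used strand is not given in the sources used here, so both values are uncertain to that extent.

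**Figure D1:**
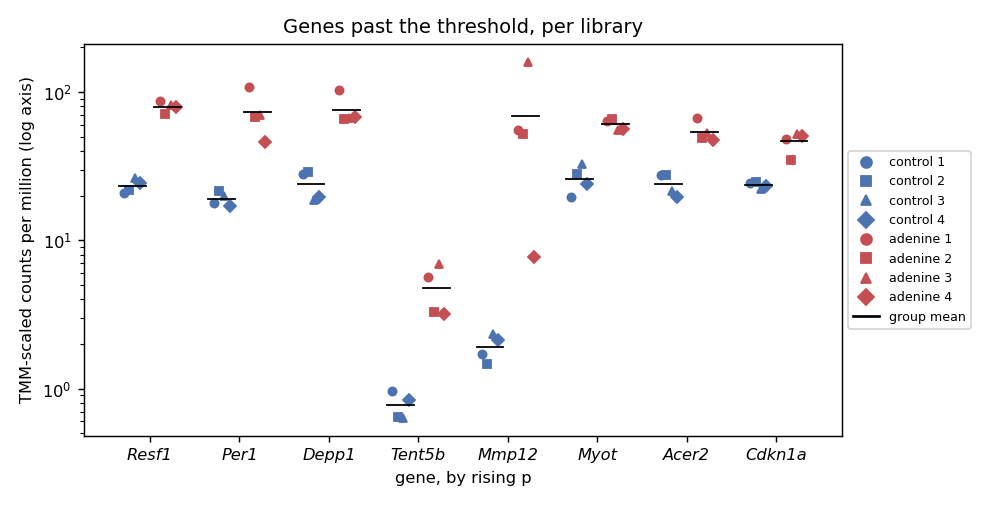
TMM-scaled CPM on a log axis (y) for the 8 genes past the threshold (x, by rising p), with 1 point per library (n = 4 per diet) and a line at each group mean. The group means of Resf1 are 23.4 and 79.6 CPM, and Mmp12 ranges from 7.70 to 160 CPM among the adenine libraries.

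No gene fell past the threshold in edgeR, although 1333 genes were lower, and 2181 higher, at an unadjusted p under 0.05, where 1005 in all would be so by chance. Genes move together across libraries, so an excess in this count or the next is not by itself a test of the diet. Neither was counted for other splits of the libraries. The libraries of the 2 diets did not overlap for 693 genes in the higher and 772 in the lower direction, 7.29% of those tested, where chance gives 2.86%. The 5 genes with the lowest p in that direction, none of them past the threshold, were Cavin2, a component of endothelial caveolae, with a log2 fold change of -0.85 (SE 0.14), Cgnl1, a junction protein, with -1.06 (SE 0.18), Smoc2, a matricellular protein, with -1.11 (SE 0.19), Hba-a2, an alpha-globin, with -2.37 (SE 0.41), and Aldh1a1, a retinaldehyde dehydrogenase, with -1.05 (SE 0.18). Their adjusted p-values were 0.0681 for Cavin2 and 0.0744 for the others. All 5 passed in DESeq2 (adjusted p = 7.56e-05 to 0.00902) and in edgeR without adenine 3 (0.00323 to 0.0411). Both rest on libraries of the main test, so passing there, here and below, is not independent support. DESeq2 also made more false calls than edgeR in the simulation. DESeq2 called 120 genes higher and 152 lower, limma-voom 5 and 0. The count in edgeR was 1 higher without control 1, control 3 or control 4, 3 higher without adenine 1, 3 higher and 2 lower without control 2, 21 higher and 6 lower without adenine 4, and 37 higher and 30 lower without adenine 3. Resf1 passed under all 22 alternatives.

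Glucocorticoid-responsive genes formed the list with the lowest p of the 46 lists tested. Of its 20 measured members, 18 had positive log2 fold changes and the median was 1.13. Per1 and Cdkn1a rose over all genes tested, and 15 members were higher and 1 lower when adjusted over the list alone. Among members that did not pass over all genes, named here after their values were seen, the log2 fold changes were 1.49 (SE 0.26) for Fkbp5, a chaperone that restrains the glucocorticoid receptor, 1.82 (SE 0.29) for Map3k6, 1.59 (SE 0.26) for Ddit4, an inhibitor of mTORC1, 1.12 (SE 0.21) for the kinase gene Sgk1 and 1.93 (SE 0.40) for Zbtb16, which had 1.17 without adenine 1. These 5 passed in DESeq2 (adjusted p = 7.56e-05 to 0.0084) and in edgeR without adenine 3 (0.00347 to 0.0429). Of the 20 members, 10 were called higher by DESeq2 and 9 by edgeR without adenine 3. Camera called the list higher, with an adjusted p of 7.7e-17, but the adjusted p = 0.334 with an estimated correlation. The list's score, its mean log2 CPM relative to the control mean, was 0.67 to 1.31 in the adenine libraries and -0.15 to 0.18 in the controls (exact two-sided permutation p = 0.0286, the smallest that 70 assignments allow).

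In the circadian clock list, 1 of 19 members, Per1, passed over all genes, and 3 were higher when adjusted over the list alone: Per1, Per2 with a log2 fold change of 1.47 and Ciart with 1.44. Dbp, a clock output gene, had 0.92 (SE 0.33) and Arntl, which encodes the activator BMAL1, -0.73 (SE 0.30), and neither passed. DESeq2 called 3 members higher, as did edgeR without adenine 3. The list was not called by camera (adjusted p = 0.146, and adjusted p = 0.765 with an estimated correlation). It was called higher with upper-quartile factors (adjusted p = 0.0296), 1 surrogate variable (0.00481) or the receptor background (0.000319), and without adenine 4 (0.0116) or both replicates 2 (0.0111).

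Of the 3 lists on redox balance, camera called none higher. None of the 27 targets of NRF2, the transcription factor of the antioxidant response, passed over all genes or when adjusted over the list alone. The median log2 fold change of these targets was -0.01, at the 99.3rd percentile of random lists matched on abundance, whose median was -0.13. Cbr1 and Me1, with the lowest p in the list, had -0.47 (SE 0.16) and -0.42 (SE 0.18). The list was not called by camera (adjusted p = 0.146, and adjusted p = 0.84 with an estimated correlation). Hmox1, a heme oxygenase and NRF2 target, had 75.5 CPM in adenine 3 and 8.41 to 12.8 CPM in the other adenine libraries, against 9.28 to 17.1 CPM in the controls.

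Antioxidant enzymes were called lower by camera (adjusted p = 0.00153), with an adjusted p = 0.716 with an estimated correlation. Their median log2 fold change of -0.17 lay at the 46.3rd percentile of random lists matched on abundance, whose median was -0.16. None of the 30 members passed over all genes or when adjusted over the list alone. The lowest p belonged to Msrb2, a methionine sulfoxide reductase, with -0.53 (SE 0.15), and to Sod3, the extracellular superoxide dismutase, with -0.35 (SE 0.16). Enzymes that produce reactive oxygen species were not called (adjusted p = 0.863, and adjusted p = 0.895 with an estimated correlation), with a positive median of 0.31 although the camera statistic pointed lower. That median lay at the 100th percentile of matched lists, whose median was -0.07, but without adenine 3 it was -0.09 and with 1 surrogate variable -0.03. Of the 22 members none passed over all genes or over the list alone in edgeR. DESeq2 called 1 lower, Nos2, the inducible nitric oxide synthase (adjusted p = 0.0273), which had -0.87 (SE 0.26) in edgeR. The antioxidant call was lost with the receptor background as a covariate (adjusted p = 0.889) and without both replicates numbered 2 (adjusted p = 0.316), and the direction turned with 1 surrogate variable (adjusted p = 0.489). For NRF2 targets, leaving out adenine 3 gave a call in the lower direction (adjusted p = 0.00756) and a median of -0.19, leaving out control 4 (0.044) or the filter (0.0225) gave that call too, and with 1 surrogate variable the median was 0.21.

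**Figure D2:**
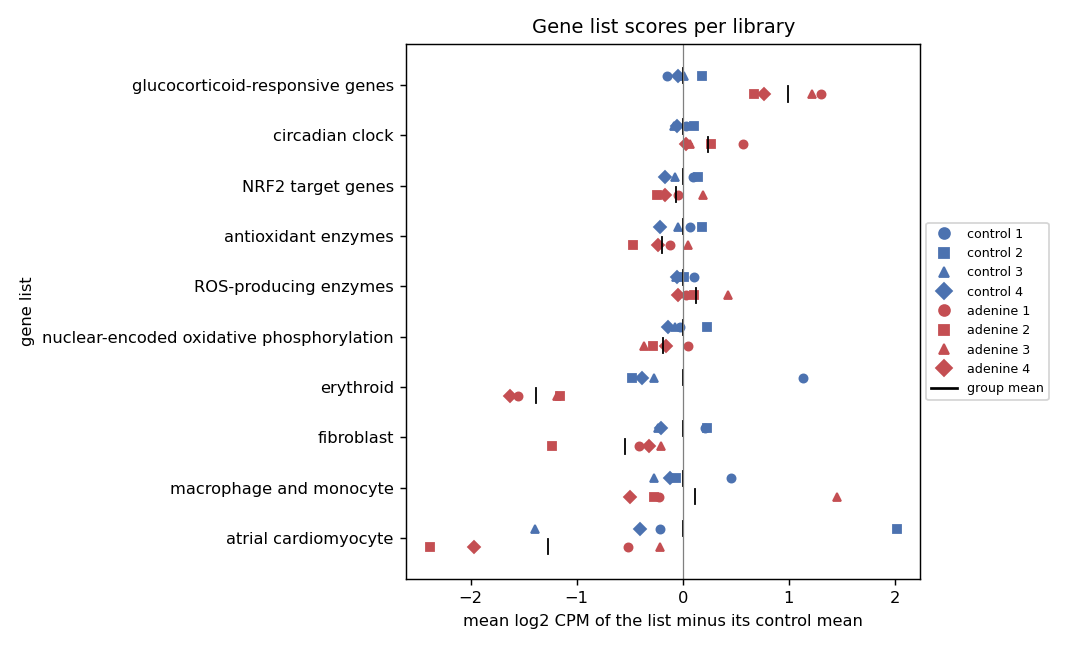
Mean log2 CPM of each gene list minus its control mean (x) for 10 lists (y), with 1 point per library (n = 4 per diet) and a line at each group mean. The glucocorticoid-responsive list is at 0.67 to 1.31 in the adenine libraries, the erythroid list is below all controls in each of them, and adenine 3 stands alone at 1.45 for macrophage and monocyte markers.

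Erythroid transcripts, which come from red blood cells and their precursors, were called lower by camera (adjusted p = 3.41e-13), with an adjusted p = 0.535 with an estimated correlation. The median log2 fold change over 10 members was -1.99, 0 members passed over all genes in edgeR, and 7 were lower when adjusted over the list alone. DESeq2 called 7 lower over all genes, as did edgeR without adenine 3. Hba-a1 had -2.34 (SE 0.41) and Hba-a2 had -2.37 (SE 0.41), near-identical copies whose reads the counting could split, and Alas2, the erythroid enzyme of heme synthesis, had -2.07 (SE 0.41). Without control 1 these 3 genes had -1.67, -1.70 and -1.36. Globin transcripts took 1.63 ± 1.23% of counts in the controls and 0.351 ± 0.0995% in the adenine libraries (SD, n = 4; exact permutation p = 0.0286, and 0.172 after adjustment over 6 library measures). The highest globin share, 3.45%, was in control 1, and the others had 0.820 to 1.18%, which is still above the adenine maximum of 0.478%.

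Fibroblast markers were called lower (adjusted p = 1.12e-06, and adjusted p = 0.623 with an estimated correlation), with a median log2 fold change of -0.65 over 14 members and 8 lower when adjusted over the list alone. Dpt, a dermatopontin of the extracellular matrix, had -1.21 (SE 0.26) and Tcf21, a fibroblast transcription factor, -1.03 (SE 0.24), while Col1a1 had 0.54 and Col1a2 had 0.89, and none of the 14 passed over all genes in edgeR. The matrix list, which holds both collagen genes, had a score of 1.44 in adenine 3 and -0.86 to -0.003 in the other adenine libraries. DESeq2 called 3 of them lower, among them Dpt (adjusted p = 0.00641) and Tcf21 (0.02), and edgeR without adenine 3 called 1. The fibroblast call was lost with 1 surrogate variable (adjusted p = 0.101). Vascular endothelial markers were called lower (adjusted p = 0.00866, and adjusted p = 0.747 with an estimated correlation), with 5 of 16 lower and 1 higher when adjusted over the list alone. The endothelial call was lost without control 4 (adjusted p = 0.0887), adenine 2 (0.0614) or adenine 3 (0.0732). Tek, the angiopoietin receptor, had -0.58 (SE 0.13), and Rgcc, a regulator of the cell cycle, had 1.24 (SE 0.22), and both passed in DESeq2 (adjusted p = 0.029 and 0.00253). Mural cell markers (adjusted p = 0.00131, and adjusted p = 0.623 with an estimated correlation) and lymphatic endothelial markers (adjusted p = 0.0271, and adjusted p = 0.716 with an estimated correlation) were called lower too. Their members included Vtn at -0.78 (SE 0.25), Cnn1 at -1.32 (SE 0.51), or -0.51 without control 2 and -0.07 with 1 surrogate variable, Ccl21a at -1.05 (SE 0.30) and Mmrn1 at -0.95 (SE 0.37). Adjusted over the list alone, 0 mural and 1 lymphatic member were lower. The lymphatic call was lost without control 2 (adjusted p = 0.125) or adenine 3 (0.0988), with 1 surrogate variable (0.155), with the receptor background as a covariate (0.121) and without both replicates 2 (0.119).

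Inflammatory and acute phase genes were called higher (adjusted p = 0.00137, and adjusted p = 0.716 with an estimated correlation). Their call was lost without adenine 3 (adjusted p = 0.155). The median log2 fold change over 34 members was 0.68, against 0.11 without adenine 3, and 6 were higher when adjusted over the list alone, among them Spp1, which encodes osteopontin, with 7.46 (SE 1.45), and Lgals3, which encodes galectin-3, with 3.27 (SE 0.70). Neither passed over all genes in edgeR (adjusted p = 0.108 and 0.128), whereas Lgals3 passed in DESeq2 (0.0289), which gave no adjusted p for Spp1. Without adenine 3, Lgals3 had 1.69 with an adjusted p of 0.00822. Spp1 was at 2730 CPM in adenine 3 and at 36.5 to 111 CPM in the other adenine libraries, against 1.52 to 8.46 CPM in the controls. Without adenine 3 its log2 fold change was 3.91 with an adjusted p of 0.000945. Macrophage and monocyte markers were not called (adjusted p = 0.798, and adjusted p = 0.939 with an estimated correlation), but without adenine 3 camera called them lower (adjusted p = 0.00151), with a median of -0.41. They were called higher with 1 surrogate variable (adjusted p = 6.46e-06) and with the receptor background (0.00345). Adenine 3 stood apart with 2065 CPM of Lyz2, the lysozyme of myeloid cells, against 146 to 256.4 CPM in the other adenine libraries and 170 to 310 CPM in the controls.

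Neutrophil markers (adjusted p = 0.00244, and adjusted p = 0.645 with an estimated correlation) and lymphocyte markers (adjusted p = 0.039, and adjusted p = 0.747 with an estimated correlation) were called higher, but their medians of 0.93 and 0.51 lay at the 88.9th and 18.5th percentile of lists matched on abundance. Csf3r had 3.16 ± 0.785 and 5.74 ± 2.003 CPM in control and adenine libraries, Mmp8 0.572 ± 0.147 and 1.39 ± 0.5004, Il7r 1.09 ± 0.484 and 6.21 ± 6.08, and Ms4a1 1.34 ± 0.405 and 2.78 ± 1.39 (SD, n = 4), none of them past the threshold. Il7r was at 15.2 CPM in adenine 3 and 1.68 to 4.53 CPM in the other adenine libraries, and its log2 fold change of 2.51 was 1.54 without adenine 3. Adjusted over the list alone, 0 neutrophil members and 1 lymphocyte member, Il7r, were higher. The lymphocyte call was lost without control 1, control 2, adenine 1, adenine 2 or adenine 4 (adjusted p = 0.0527 to 0.193). Upper-quartile factors (0.0866), no filter (0.0889), 1 surrogate variable (0.719, with a median of -0.12), the receptor background (0.573) and removal of both replicates 2 (0.208) ended it too. Reads on 1472 olfactory and vomeronasal receptor genes, which are known from sensory neurons, summed to 369 to 924 unscaled CPM in the controls and 667 to 2103 unscaled CPM in the adenine libraries. The diets did not differ by an exact two-sided permutation test (p = 0.229). Adenine 1 and adenine 3, at 667 and 688, lay within the control range.

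Of the lists of cardiomyocyte function, those of oxidative phosphorylation, fatty acid oxidation, calcium handling and heat shock were called lower. Sarcomere (adjusted p = 0.225), glycolysis (0.127), PPAR alpha (0.508) and mitochondrially encoded genes (0.468) were not called, with adjusted p = 0.84 to 0.895 with an estimated correlation. Nuclear-encoded oxidative phosphorylation genes had a median log2 fold change of -0.19, negative in all 41 members (adjusted p = 0.000146, and adjusted p = 0.747 with an estimated correlation), against -0.17 in lists matched on abundance. Cox7a1 had -0.52 (SE 0.20) and Cox8b -0.40 (SE 0.18). Fatty acid oxidation genes had a median of -0.24 (adjusted p = 0.00231, and adjusted p = 0.747 with an estimated correlation), with Cpt2 at -0.37 (SE 0.15) and Acads at -0.40 (SE 0.17). That call was lost without control 2 (adjusted p = 0.0929). Calcium handling and ion channel genes had -0.21 (adjusted p = 1.85e-05, and adjusted p = 0.716 with an estimated correlation), with 4 lower when adjusted over the list alone, including the potassium channel genes Kcnd2 at -0.96 (SE 0.22) and Kcnj2 at -0.72 (SE 0.19), which passed in DESeq2 (adjusted p = 0.0273 and 0.041). Heat shock genes had -0.33 (adjusted p = 1.26e-05, and adjusted p = 0.716 with an estimated correlation), with the chaperone genes Hspd1 at -0.49 (SE 0.16) and Chordc1 at -0.44 (SE 0.15). Among lists matched on abundance, the calcium handling median lay at the 5.88th percentile (matched median -0.155), so it was not clearly lower than in such lists. The fatty acid oxidation median lay at the 2.7th percentile and the heat shock median at the 0.03rd. With 1 surrogate variable, with the receptor background as a covariate and without both replicates 2, the phosphorylation call was lost (adjusted p = 0.074, 0.111 and 0.0882), as was that of fatty acid oxidation (adjusted p = 0.496, 0.452 and 0.217). In the phosphorylation, fatty acid oxidation and heat shock lists, 0 members were lower when adjusted over the list alone.

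Ventricular cardiomyocyte markers had a median of -0.15, against -0.16 in matched lists (adjusted p = 0.0173, and adjusted p = 0.747 with an estimated correlation), with Actc1 at -0.46 (SE 0.24) and Nkx2-5 at -0.48 (SE 0.18). Without control 2 or adenine 3 the ventricular call was lost (adjusted p = 0.0698 and 0.164). It was also lost with 1 surrogate variable (0.101), the receptor background (0.172) and both replicates 2 out (0.132). Atrial markers had a median of -1.49 (adjusted p = 0.000123, and adjusted p = 0.716 with an estimated correlation), with Stard10 at -1.87 (SE 0.53), or -0.86 without control 2, and Kcnj3 at -0.87 (SE 0.26). The atrial call was lost with 1 surrogate variable (adjusted p = 0.582), where the median was 0.04, with the receptor background as a covariate (0.29) and without both replicates 2 (0.197). Of the 11 atrial markers, 3 were lower when adjusted over the list alone, against 0 ventricular markers. The atrial light chain gene Myl4 was at 2054 CPM in control 2, at 23.5 to 256.1 CPM in the other controls, at 188 and 231 CPM in adenine 1 and adenine 3, and at 6.85 and 7.74 CPM in adenine 2 and adenine 4. Its log2 fold change of -2.52 was -0.38 without control 2. The cardiac stress list was not called (adjusted p = 0.573, and adjusted p = 0.895 with an estimated correlation). Its direction turned, and camera called it higher, with 1 surrogate variable (adjusted p = 0.00552) and without both replicates 2 (0.00542). Its member Nppb, which encodes a natriuretic peptide released by strained myocardium, was at 181 ± 33.2 CPM in the controls and 494 ± 317 CPM in the adenine libraries (log2 fold change 1.45, SE 0.40, adjusted p = 0.207). Acta2 had -0.91 (SE 0.40), or -0.20 with 1 surrogate variable, and Nppa, chosen after its values were seen, 0.16 (SE 0.58).

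The remaining called lists were lower as well. Interferon-stimulated genes (adjusted p = 0.000903, and adjusted p = 0.747 with an estimated correlation) included Gbp2 at -0.70 (SE 0.16) and Rsad2 at -1.04 (SE 0.28). The list's score was 0.42 in adenine 3, above all controls (-0.37 to 0.18), and -0.44 to -0.39 in the other adenine libraries. Without adenine 3 the list's median was -0.48 instead of -0.16, and Gbp2 and Rsad2 passed in edgeR (adjusted p = 0.0263 and 0.0429). Genes of cholesterol and fatty acid synthesis (adjusted p = 0.00131, and adjusted p = 0.716 with an estimated correlation) included Scd2 at -0.88 (SE 0.26) and Stard4 at -0.49 (SE 0.16). Cell cycle genes (adjusted p = 0.00352, and adjusted p = 0.799 with an estimated correlation) included Cenpf at -1.28 (SE 0.30) and Cenpa at -0.50 (SE 0.14). Renin-angiotensin and natriuretic signalling genes (adjusted p = 0.0306, and adjusted p = 0.716 with an estimated correlation) included Hsd11b1 at -0.43 (SE 0.13) and Npr3 at -0.87 (SE 0.27). Muscle atrophy and autophagy genes (adjusted p = 0.0471, and adjusted p = 0.747 with an estimated correlation) included Cited4 at -1.22 (SE 0.25) and Foxo4 at -0.60 (SE 0.16). In DESeq2, Rsad2, Cenpf and Cited4 passed over all genes (adjusted p = 0.0425, 0.00995 and 0.00159). The medians of the interferon, cholesterol and cell cycle lists lay at the 3.23rd percentile or below among lists matched on abundance. The atrophy median of -0.11 lay above the matched median of -0.15, at the 84.9th percentile, and the renin-angiotensin median lay at the 52.0th. In all, camera called 4 lists higher and 17 lower of 46, and 0 lists were called with an estimated correlation or by fry. In the cell cycle list 1 member was lower when adjusted over the list alone, in the interferon list and in the atrophy list 2 each, and in the cholesterol and renin-angiotensin lists 0. The cell cycle call was lost without control 1 (adjusted p = 0.572) or adenine 4 (0.0622). The atrophy call was lost without control 2 (adjusted p = 0.317), adenine 2 (0.0858) or adenine 4 (0.0584). Upper-quartile factors (0.144), the replicate block (0.067), the receptor background (0.889) and removal of both replicates 2 (0.705) ended it too, and it turned with 1 surrogate variable (0.807). The renin-angiotensin call was lost without control 2 (adjusted p = 0.155), adenine 3 (0.0808) or adenine 4 (0.0622). Adjusted p-values were 0.275 with 1 surrogate variable, 0.332 with the receptor background and 0.159 without both replicates 2. The surrogate variable also ended the interferon (0.112) and cholesterol (0.105) calls, and the receptor background the latter (0.0584).

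The log2 fold changes depended on abundance. Their median was 0.81 over the 3842 genes under 1 CPM, 0.585 over the 4859 genes at 1 to 4 CPM and -0.15 over the 4836 genes at 16 to 64 CPM. Across genes, which are not independent replicates, the Spearman correlation of fold change and abundance was -0.656. The libraries did not separate by diet on principal component 1, which held 58.9% of the variance (difference of group means 25.6, exact two-sided permutation p = 0.114). On principal component 2, which held 20.9%, the difference was 14.2 (exact permutation p = 0.0286), with adenine 3 at 31.1 and the other adenine libraries at -4.52 to 4.22. The controls lay at -9.99 to -4.59, so the highest control and the lowest adenine library nearly met. Upper-quartile scaling moved the median of all genes from 0.05 to 0.20 on the log2 scale.

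**Figure D3:**
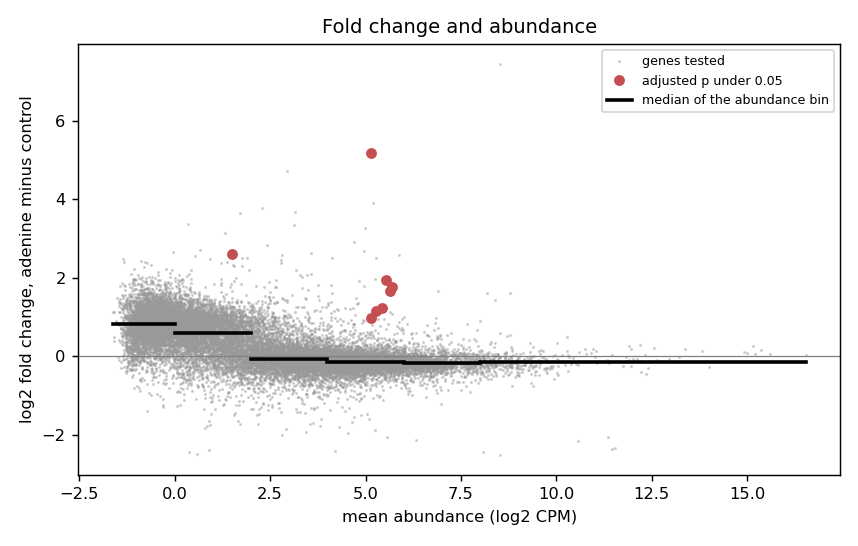
Log2 fold change, adenine minus control (y), against mean abundance in log2 CPM (x) for the 20093 genes tested, with the 8 genes past the threshold in red and the median of each abundance bin as a black line. The medians fall from 0.81 under 1 CPM to -0.15 at 16 to 64 CPM.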

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

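Tests chosen only after the result was seen were those of the clock genes, of the abundance and background effect on the glucocorticoid-responsive list, and of added tissue and of a control heart under the label in adenine 3. Within each diet, single libraries far from the other 3 were looked for among library measures, list scores, components and named genes, and 29 of 266 groups of values held one, where chance gives about 1 in 20, or 13.3. Some of the named genes had been chosen after their values were seen, and items such as the globin share and the erythroid genes overlap. The excess over 13.3 is therefore not a test. Of the 29, 12 were in control 1 and 9 in adenine 3.

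Adenine 3 stood apart in scores of macrophage and monocyte markers (1.45, others -0.50 to -0.22), antigen presentation (0.68, others -0.09 to -0.07) and interferon-stimulated genes (0.42, others -0.44 to -0.39). It also stood apart in Spp1 at 2730 CPM, Lyz2 at 2065, Lgals3 at 170, Hmox1 at 75.5, Ccr2 at 50.4 and Atp6v0d2 at 25.3 CPM, against at most 111, 256.4, 28.9, 12.8, 8.07 and 4.53 CPM in the other adenine libraries. In control 1, globin took 3.45% of counts, and the erythroid score was 1.14, with Hba-a1 at 10540, Hba-a2 at 10100, Alas2 at 166 and Bpgm at 90.4 CPM. Control 1 was lowest in mitochondrial counts, at 31.0%, and in the share of its 10 most abundant genes, at 31.9%, and highest among controls in Col6a2 at 106, Cenpa at 28.9, Hmox1 at 17.1 and Gbp2 at 16.9 CPM. Control 2 was highest in Myl4 at 2054, Myl7 at 1532 and Kcnj3 at 93.8 CPM and lowest in the neutrophil score, at -0.39. Adenine 1 was highest in Depp1 at 103.4, Zbtb16 at 99.2, Rgcc at 52.8 and Map3k6 at 36.1 CPM.

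The place of adenine 3 was weighed against a wrong label and against added tissue. Of 67 genes called without it, it lay on the adenine side of the midpoint between the diets for 70.1%. That is between the 50% and 80% set beforehand, and the SE of 5.59 treats the genes as independent. Its score of the glucocorticoid-responsive list, 1.22 against at most 0.18 in the controls (SD 0.139), and Resf1, called without it as well, at 81.9 CPM against at most 26.4 CPM in the controls, argue against a control heart under an adenine label. Added tissue that expresses none of the 16 ventricular markers would lower them by a common factor. Their log2 ratios to the other adenine libraries had an SD of 0.457, above the 0.181 to 0.299 of the other 7 libraries. They ran from -1.29 for Myh6 to 0.63 for Tbx20. That argues against dilution by such tissue as the whole cause. Added tissue that expresses some of these markers was not tested and stays open. A more severe response to the diet stays open, as do a change in the cells added and a sample from outside both diets, which cannot be told apart since no other group was measured.

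The rise of glucocorticoid-responsive genes was weighed against the abundance trend and the hour of collection. With the receptor background as a covariate the list's median log2 fold change was 1.18, against 1.13 without it. Its SE of 0.241 was taken over the 20 members as if independent, not over libraries. Without the covariate the median lay at the 100th percentile of lists matched on abundance. Both medians argue against the abundance trend as the cause. If the diets were sampled at different hours, clock genes of opposite phase would move apart. The difference of 8 clock genes and 5 genes of opposite phase was 0.81 higher in the adenine libraries (log2, exact permutation p = 0.0857; -0.13 in adenine 4 and 0.81 to 1.73 in the others). A response of the clock genes to the diet would move them apart too, and the labels do not give the hour. Hour of collection therefore cannot be told apart from a response to the diet. In 4 of the 35 splits of the 8 libraries into 4 and 4, the real one included, camera gave this list a p as small (1.67e-18 for the diets, 3.52e-29 at the lowest among the others), so chance could not be excluded by this count, although each of the 3 others kept 3 adenine libraries together and so held part of the diet difference.

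The fall of fold change with abundance was weighed against background reads, depth and base composition. Its Spearman correlation across genes, -0.654 to -0.655 on the genes each correction covered, became -0.397 after subtracting each library's receptor reads per kb, -0.633 after thinning to the smallest total and -0.594 after removing GC and length trends, each keeping more than -0.327 by more than its spread over left-out libraries. The values for depth and for GC and length argue against each of these as the whole cause. For background, -0.397 lies close to -0.327, and the spread over left-out libraries (SD 0.0454) understates the error. Over genes above 16 CPM, subtraction took the correlation from -0.0613 to 0.0157. Subtraction also assumed 1 background rate per kb for every gene. With the receptor background as a covariate the correlation was -0.192, and with 1 surrogate variable estimated from the counts -0.0779. A difference between libraries, background included, therefore stays open as part or all of the cause. In 6 of the 35 splits the correlation was as large in size (0.656 for the diets, 0.726 at the highest among the others), so chance could not be excluded.

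In 2 of the 35 splits at least as many genes were called, 8 for the diets and 547 for the other, which set adenine 3 with controls 1, 2 and 3 against the rest and points to a structure of the samples, so chance could not be excluded for the count. For the number of called lists, 22 of the 35 splits gave as many (21 for the diets, 31 at the highest among the others), and chance could not be excluded. For erythroid genes, 1 of the 35 splits, the diets themselves, gave a p as small (1.48e-14, against 7.48e-13 at the lowest among the others), the smallest share that 35 splits allow. That argues against chance for this list taken alone, but it was picked for its low p among 46 lists, and its adjusted p = 0.535 with an estimated correlation.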

How the results depend on the processing

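Receptor background as a covariate, removal of both replicates 2, GC and length correction and thinning were chosen after seeing the data. Main counts were 8 genes higher, 0 lower and 21 lists, and causes were not tested unless stated. Genes higher and lower numbered 18 and 1 with upper-quartile factors, 120 and 152 with the DESeq2 Wald test, 5 and 0 with limma-voom, 12 and 6 with robust edgeR, and 8 and 1 with no low-count filter. They numbered 38 and 4 with 1 surrogate variable, 20 and 2 with the receptor background, 6 and 1 without both replicates 2, 2 and 0 after GC and length correction, 21 and 10 at an adjusted p under 0.1, and 3 and 0 at 0.01. Leaving out single libraries gave 1 to 37 higher and 0 to 30 lower. All 8 genes passed in DESeq2, with upper-quartile factors and without adenine 3, and Resf1 in all 22 alternatives. The replicate number as a block gave 16 and 16. Correlations of same-numbered libraries were 0.086, -0.5, -0.16 and 0.3, and libraries did not all correlate best with their own number, so the numbers were not taken to pair the samples. Lists called numbered 0 with an estimated correlation and 0 with fry, whose question differs, and 16 to 25 with single libraries left out. Separation on principal component 1 stayed short of the threshold under both its alternatives (exact permutation p = 0.114 to 0.143). Of the 21 called lists, 12 kept the call without each single library and 9 lost it without at least 1.

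Log2 fold changes that turned were Nppa at -0.41 in limma-voom, -0.20 under the block and -0.48 to 0.53 with single libraries left out, Myl4 and Myl7 at 0.048 and 0.14 with the surrogate variable and 0.013 and 0.21 without both replicates 2, and, over left-out libraries, Lyz2 at -0.15 to 2.005 and Hmox1 at -0.19 to 1.55, lowest without adenine 3.

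List values are adjusted p-values by camera, in the opposite direction to the main result unless stated. Antioxidant enzymes had 0.716 with an estimated correlation and 0.438 by fry, and with the receptor background 0.889 and without both replicates 2 0.316, all in the main direction, and 0.489 with the surrogate variable. In the order surrogate variable, receptor background, both replicates 2 out, values were 0.0652, 0.254 and 0.786 for NRF2 targets, 0.184, 0.405 and 0.774 for ROS-producing enzymes, 0.0122, 0.0195 and 0.257 for metal ion response, 8.1e-12, 6.81e-05 and 0.00753 for matrix, 0.00552, 0.0584 and 0.00542 for cardiac stress, 0.0332, 0.0517 and 0.0462 for PPAR alpha targets, and 0.184, 0.308 and 0.636 for glycolysis. In the same order they were 0.00742, 0.0187 and 0.109 for unfolded protein response, 0.105, 0.273 and 0.567 for purine metabolism, and 1.23e-07, 6.81e-05 and 0.00606 for ribosomal proteins. Sarcomere genes had 0.963 and 0.786 under the last 2 of these, and with the surrogate variable atrophy had 0.807 and epicardium 0.704. Upper-quartile factors gave 0.995 for ribosomal proteins and for macrophages. No filter gave 0.848 for antigen presentation and 0.883 for p53 targets, aryl hydrocarbon receptor targets and macrophages, and 0.0225 for NRF2 targets in the main direction. In the same order and in the main direction, calls were gained by hypoxia (0.000171, 0.000357 and 0.00542), immediate early (1.73e-07, 6.81e-05 and 0.00126), p53 (0.00197, 0.0171 and 0.0462) and adipocyte genes (0.0328, 0.00889 and 0.00139). Conduction system, epicardial, mineral metabolism, sarcomere, glycolysis and neighbouring-tissue lists gained calls under other settings (0.00105 to 0.0492). Fry gave 0.809 for ROS-producing enzymes and 0.999 for matrix.

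With single libraries left out, lists that turned or crossed the threshold ranged from 0.00756 to 0.611 (NRF2), 0.283 to 0.868 (ROS), 0.114 to 0.903 (metal ion), 4.26e-05 to 0.957 (matrix), 0.117 to 0.989 (cardiac stress), 0.142 to 0.821 (PPAR alpha), 0.147 to 0.991 (mitochondrial transcripts), 0.0379 to 0.828 (unfolded protein), 0.0216 to 0.96 (immediate early), 0.0808 to 0.882 (antigen presentation), 0.0858 to 0.974 (p53), 0.691 to 0.967 (aryl hydrocarbon receptor), 0.00151 to 0.929 (ribosomal), 0.00151 to 0.974 (macrophage) and 0.0296 to 0.902 (adipocyte). Over all alternatives, named genes kept direction and side of the threshold in 1561 values, lost the call in 51, gained it in 111 and turned in 10, and for lists these numbers were 573, 97, 45 and 67. Depth limits genes near 1 CPM, which rest on few reads in adenine 2.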

Other observations

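The hypothesis and its test in this part were chosen after the values were seen. Besides Mmp12, Spp1 and Lgals3, 3 further genes of lipid-handling and bone-resorbing macrophages were higher in all 4 adenine libraries than in all 4 controls, without passing over all genes in edgeR. Gpnmb was at 4.58 ± 0.472 CPM in the controls and 67.9 ± 84.9 CPM in the adenine libraries (SD, n = 4), with a log2 fold change of 3.89 (SE 0.71, edgeR adjusted p = 0.0805). Itgax, which encodes CD11c, had 3.34 (SE 0.54, adjusted p = 0.0585) and Atp6v0d2, a subunit of the proton pump, 3.78 (SE 0.70, adjusted p = 0.0808). Adenine 3 was highest in each, with Gpnmb at 194 CPM, and adenine 4 was lowest of the adenine libraries, with 10.2 CPM. Without adenine 3 the log2 fold changes were 2.49 for Gpnmb, 2.55 for Itgax and 2.40 for Atp6v0d2, and all 3 passed (adjusted p = 0.0023, 0.00404 and 0.00901), as they did in DESeq2 with all libraries (0.00384, 0.00149 and 0.00372).

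A candidate explanation is a larger number of macrophages of the kind already present, in which case the 18 macrophage and monocyte markers would rise alongside. Without adenine 3, the 6 genes were higher by 2.7 on the log2 scale. They were picked for that rise, so no p-value is given for it. The 18 markers, fixed beforehand, differed by -0.33 (exact two-sided permutation p = 0.143). At the preset correlation, camera called them lower without adenine 3 (adjusted p = 0.00151). With all libraries it called them higher with 1 surrogate variable (adjusted p = 6.46e-06) and with the receptor background (0.00345). The 6 genes exceeded the markers by at least 2.19 in each of adenine 1, adenine 2 and adenine 4, against at most 0.54 in size among the controls. Their choice favours such an excess, so the weight lies on the markers. The marker score was -0.50 to -0.22 in these 3 libraries and -0.27 to 0.45 in the controls. Without adjustment for other differences between libraries, that argues against more macrophages of that kind in these 3 libraries. A small number of cells in another state, which markers with a high baseline would not show, may still be the source, and stays open as a hypothesis. In adenine 3 the markers were 1.45 above the control mean, and both changes were seen together.

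The metal-binding gene Mt2 was at 0.798 ± 0.217 CPM in the controls and 4.16 ± 3.51 CPM in the adenine libraries (SD, n = 4; log2 fold change 2.39, SE 0.55, edgeR adjusted p = 0.142, DESeq2 adjusted p = 0.00201; 1.72 without adenine 3), and the list of metallothioneins and metal ion response was not called (adjusted p = 0.444, and adjusted p = 0.878 with an estimated correlation), although it turned and was called higher with 1 surrogate variable (adjusted p = 0.0122) and with the receptor background (0.0195). Among matrix genes, Timp1 had 2.50 (SE 0.65) and Col6a2 -0.80 (SE 0.20), neither past the threshold in edgeR. Timp1 was at 83.1 CPM in adenine 3 and 5.99 to 19.2 CPM in the other adenine libraries, and without adenine 3 it had 1.16. The matrix list had a positive median of 0.31 although the camera statistic pointed lower (adjusted p = 0.54, and adjusted p = 0.91 with an estimated correlation). Without adenine 3 its median was -0.33 and camera called it lower (adjusted p = 4.26e-05). It was called higher with 1 surrogate variable (8.1e-12), with the receptor background (6.81e-05), without adenine 2 (0.00683) and without both replicates 2 (0.00753). Median and camera direction differed in sign also for PPAR alpha targets, the cardiac stress list and cytosolic ribosomal proteins, and mean and direction for purine metabolism, the unfolded protein response, metal ion response and adipocyte markers. The adjusted p-values by camera of the 25 lists that were not called ranged from 0.0592 to 0.869.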
